A study of Arabidopsis thaliana with 8 samples.

How the data were processed

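Total RNA from 8 samples of wild-type Arabidopsis thaliana, ecotype Landsberg, was compared, 4 samples under red light and 4 under white light, per the labels. The deposited values are probe intensities on a linear scale, with 1 column per sample, many values of exactly 0 and a ceiling at 100. The background correction, scaling and any filter behind the deposited intensity values are not given in the sources used here, nor is a genome build, so that no coordinates are printed. The columns differ in total and in median, which shows that they do not share 1 fixed total. The number of arrays limits the precision, and intensities near the lower end of the scale carry no information on order.

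Probes were named from the platform annotation, which is old and was not checked against probe sequences, and gene names were looked up in a table of the TAIR10.1 assembly used for names only. Of 692 probes with 1 gene, 690 matched a gene of that table, and the other 2 kept their annotated name. The 870 probes of several genes and the 1877 without a gene were tested but not named. AT2G25870 was the 1 gene with 2 probes.

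The arrays were quantile-normalized, values below a floor were set to the floor, and log2 values were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, red minus white, two-sided, with Benjamini-Hochberg adjustment. Folds in the text come from these normalized values, while intensities are on the deposited scale, so that their ratios differ. The rule chosen before the data were examined set values at or under 0 to the 5th percentile of the positive values of their array and tested every probe. As fitted here, with that percentile as a floor for each array, positive values below the floor were raised to it as well. After normalization these floors lay between 0.0654 and 0.0716 on the red arrays and between 0.0234 and 0.0385 on the white arrays. They gave a difference to probes at 0 on all arrays. The reported fit therefore uses 1 floor for all arrays, 0.0716, the highest of the 8, and leaves out 407 probes at the floor on all 8 arrays. This change was made after seeing the data, and the counts under the first rule, fitted in that way, are given beside the reported ones. A fold against a group at the floor on all of its arrays is written as "at least".

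The genes named follow a rule chosen before the data were examined. It takes the 12 largest rises and the 12 largest falls among called probes of 1 gene whose groups do not overlap, and up to 4 members with the lowest p from each of the gene lists. The rule also asks for 12 light-response and photosynthesis genes, such as CHS and PHYB, none of which had a probe of its own. The lists cover the antenna, both photosystems, electron transport, the Calvin cycle, photorespiration, chlorophyll, carotenoids, flavonoids, light stress, photoreceptors and the clock, antioxidants, plastid chaperones and import, starch, nitrogen and sulfur assimilation, and markers of non-green tissue and senescence. No list had the 5 measured members that a camera test (preset correlation 0.01) was to require. Lists drawn later from the symbols on the array were tested in their place.

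Same-numbered samples of the 2 groups, numbered in the labels, deviated together from their group means. Their correlations across probes ran from 0.239 to 0.320, all over 0.1, against -0.206 to 0.107 for samples of different groups and different numbers. The replicate number was therefore also fitted as a block. It is the data, not the labels, that tie these samples. Within a group these correlations were 0.334 to 0.470 for samples 1 and 2 or samples 3 and 4. They were -0.723 to -0.671 between those pairs. Alternatives were the scale as deposited, median centring, an offset in place of the floor, a higher floor, a filter on dim probes, a variance trend with robust fitting, array weights, averaging of probes, leaving out each sample, and fits that treat samples 1 and 2, and 3 and 4, of a group as pairs.

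The fit was tested on simulated data of 4 independent samples per group, in which 100 probes changed 2-fold and 100 changed 4-fold. It recovered 29 of 98 tested probes with a 2-fold change and 70 of 98 with a 4-fold change, all with the right sign, and 8 of 107 calls were unchanged probes. With no effect and deviations shared within pairs, over 20 simulated sets of 2964 probes, the fit of 4 against 4 called 109.1 probes on average (83 to 162), the random block 8.4 and averaged pairs 0. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.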

Results

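Transcript abundance was measured in wild-type Arabidopsis thaliana of the Landsberg ecotype, a laboratory strain, after 48 h under red light or under white light, both at 20 µE. Each light condition had 4 samples, and each sample of total RNA has 1 column of intensities for 3439 probes. Each column is called an array below, although the labels do not say whether each was a separate hybridization. Of these probes, 692 are paired with 1 gene, 870 with several genes and 1877 with no gene in the annotation used here, so that genes are named below only for the first of these classes. Summed intensity per sample ranged from 1691 to 3196 in the arbitrary units of the table, and the number of arrays limits the precision. The labels do not say whether the samples came from separate plants or cultures, so that the p-values measure only the spread between these samples, which may be technical.

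The comparison asks which transcripts differ between plants kept in red light and plants kept in white light of the same stated intensity. Among the genes that were higher in red light, AT1G78620, which encodes a phytyl phosphate kinase of tocopherol synthesis, rose 6.75-fold, from an intensity of 0.231 ± 0.0651 in white light to 1.59 ± 0.678 in red light (SD, n = 4 each; log2 fold change 2.76 ± 0.28, SE; limma adjusted p = 0.00103). AT1G06730 rose 5.88-fold, from 0.331 ± 0.0190 to 2.25 ± 0.478 (log2 fold change 2.56 ± 0.28, adjusted p = 0.00106). AT4G13680 had the largest fitted rise, with a log2 fold change of 3.25 ± 0.52 (adjusted p = 0.00366), but it was listed at or below the floor in 3 of the 4 white samples. Its rank depends on the floor. With the floor at the 20th percentile AT1G78620 (2.74), AT1G06730 (2.56) and AT5G40030 (2.46) lay above AT4G13680 (2.37). AT5G40030 rose 6.39-fold and AT4G04370 rose 6.18-fold. AT4G17070 rose 4.07-fold, from 1.48 ± 0.120 in white light to 10.1 ± 4.74 in red light. The other 6 were AT2G14660, AT5G38310, AT2G04790, AT2G31920, AT3G02690 and AT1G12800, which rose 4.29-fold to 5.07-fold. White arrays at or below the floor numbered 2 for AT2G31920, 2 for AT3G02690 and 1 for AT4G04370, so that the floor enters their folds. These genes were chosen among those whose red and white samples did not overlap. The SE and adjusted p given here take the 4 samples of a group as independent. With the pair of similar samples as a random block, limma adjusted p was 0.0270 for AT1G78620, 0.0237 for AT1G06730 and 0.197 for AT4G13680. With each pair averaged to 1 value none of the named genes passed in limma (lowest adjusted p = 0.181). Under other treatments of low values the log2 fold change was 2.37 (higher floor) or 4.24 (floor per array) for AT4G13680, 1.92 (offset) for AT4G04370, 1.64 (offset) for AT5G38310, and 1.41 (offset) or 1.24 (higher floor) for AT2G31920. That of AT4G17070 was 2.79 with median centring.

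Among the genes that were lower in red light, AT5G59060 fell by 2.92 on the log2 scale (SE 0.37, adjusted p = 0.00138), from 0.633 ± 0.192 in white light to 0.0620 ± 0.0287 in red light. AT1G29070, which encodes a ribosomal protein of the plastid, fell by 2.28 (SE 0.29, adjusted p = 0.00144), from 0.832 ± 0.433 to 0.149 ± 0.0405. AT4G37230 was at or below the floor on all 4 red arrays and was at least 4.28-fold lower there (adjusted p = 0.00197), a bound that depends on the floor, since the log2 fold change was -1.05 (adjusted p = 0.0287) with the floor at the 20th percentile. AT2G46910, a member of the plastid fibrillin family, fell by 2.09, a size set in part by the floor, since 2 of its 4 red arrays lay there, and the change was -3.12 in samples 1 and 2 and -1.05 in samples 3 and 4. AT1G02020 also fell by 2.09. The glutamate receptor-like gene GLR2.7 (AT2G29120) fell by 1.72, from 0.944 ± 0.182 to 0.306 ± 0.0428. AT1G71910, AT1G04420, AT1G70180 and AT2G22890 had log2 fold changes from -1.85 to -1.70. AT-HF (AT4G26900), an enzyme of histidine synthesis, had a log2 fold change of -1.78 (adjusted p = 0.0366). Leaving out any of the 4 red samples or white sample 2 ended that call, with adjusted p between 0.0553 and 0.0846. White sample 1 had an intensity of 1.41 for AT-HF, against 0.450 to 0.472 in the other white samples. Without it the log2 fold change of AT-HF was -1.28 (adjusted p = 0.0210). AT1G51350 had a log2 fold change of -1.69 (adjusted p = 0.0191), which became -0.94 (adjusted p = 0.201) on the deposited scale and -0.74 (adjusted p = 0.216) with arrays centred on their medians. With an offset or the higher floor, the log2 fold change was -2.08 or -2.20 for AT5G59060 and -1.14 or -0.95 for AT1G70180, each of which had 1 red array at or below the floor. With the pair as a random block, limma adjusted p was 0.0672 for AT5G59060, 0.0880 for AT1G29070 and 0.0383 for AT4G37230. In that fit it was 0.352 for AT-HF and 0.0920 for AT1G51350.

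**Figure D1:**
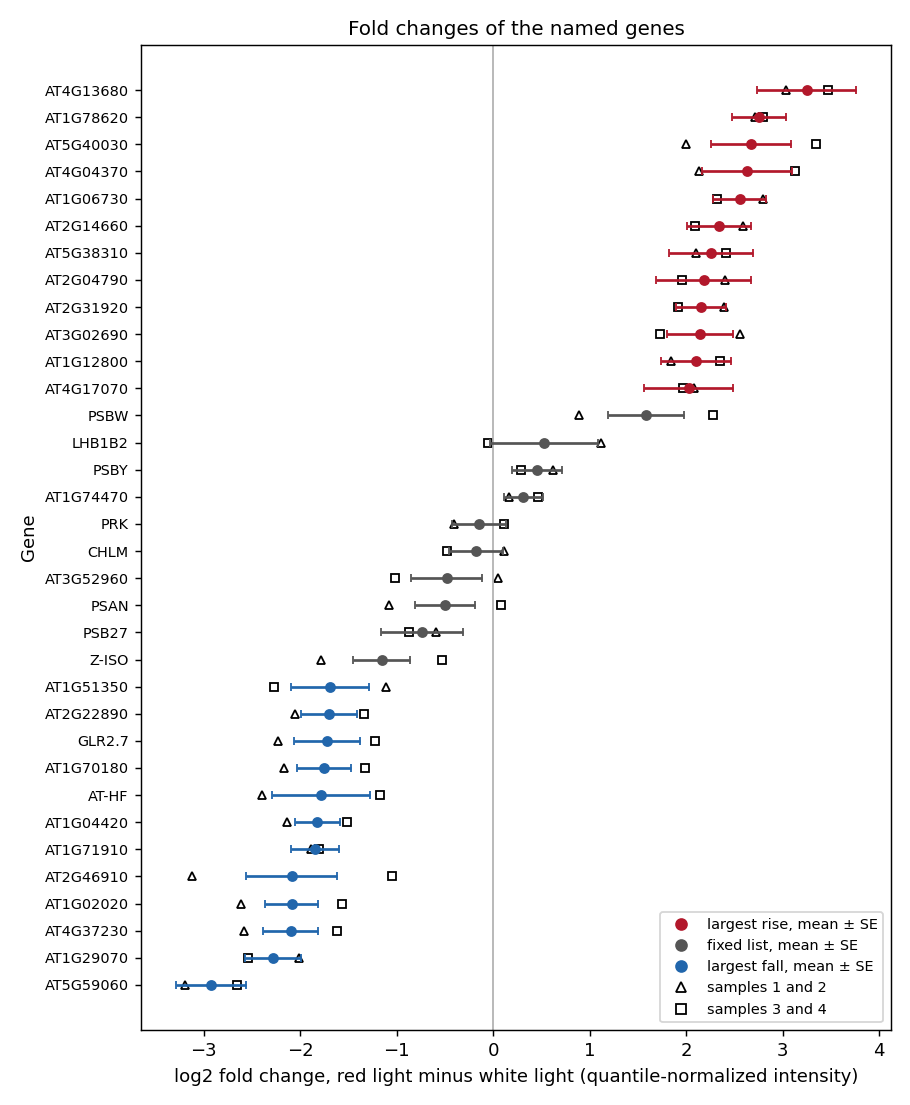
The horizontal axis gives the log2 fold change of each named gene, red light minus white light, and the vertical axis lists the genes. Filled points with bars are the fitted change and its limma SE, with the 4 samples per group taken as independent. Triangles are samples 1 and 2, squares are samples 3 and 4, and fitted changes run from 3.25 for AT4G13680 to -2.92 for AT5G59060. For AT2G46910 the sets gave -3.12 and -1.05.

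For photosynthesis and pigment synthesis the arrays gave a thin view, since 11 of the 289 genes listed before the data were examined were measured by a probe of their own. Of these 11 genes, 1 rose, 1 fell, 8 did not pass the test and 1 was not tested, and the same number of calls, 2, was found when p was adjusted over the list alone. PSBW, a small subunit of photosystem II, rose, with a log2 fold change of 1.58 ± 0.39 (adjusted p = 0.0222) and intensities of 67.5 ± 37.5 in red light and 11.1 ± 2.95 in white light, and 2 of the red arrays were at the ceiling of the scale, so that the size of the rise was not measured there. Its log2 fold change was 2.45 on the deposited scale, 2.65 with median centring, 0.89 in samples 1 and 2 alone and 2.27 in samples 3 and 4 alone. Its call was lost without white sample 1 (adjusted p = 0.0538), red sample 3 (0.0506) or red sample 4 (0.0589). Z-ISO, an isomerase of carotenoid synthesis, fell by 1.16 on the log2 scale (SE 0.29, adjusted p = 0.0232), with -1.78 in samples 1 and 2 alone and -0.53 in samples 3 and 4 alone. That call was lost without sample 1 or sample 2 of either group, with adjusted p from 0.0572 to 0.0594. It was also lost on the deposited scale (adjusted p = 0.0665) and with median centring (adjusted p = 0.0581).

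The other photosystem II genes did not pass the test, with log2 fold changes of 0.45 ± 0.26 (adjusted p = 0.232) for PSBY, which was 0.94 with median centring (adjusted p = 0.0525), and -0.74 ± 0.42 (adjusted p = 0.234) for the assembly factor PSB27. With the replicate number as a block, the adjusted p of PSB27 was 0.0321, and with the pair of samples as a random block it was 0.446. The antenna gene LHB1B2, also called LHCB1.5, had a log2 fold change of 0.53 ± 0.56 (adjusted p = 0.528), which was 1.34 on the deposited scale (adjusted p = 0.173) and 1.54 with median centring (adjusted p = 0.0693). After quantile normalization it was 1.12 in samples 1 and 2 alone (adjusted p = 0.0101, by a test that rests on the spread between those 2 samples) and -0.06 in samples 3 and 4 alone. The intensities of LHB1B2 as deposited were 24.8 and 21.8 in red samples 3 and 4, against 14.7 and 13.8 in white samples 3 and 4. The lack of a difference in samples 3 and 4 thus depended on the scaling. The photosystem I gene PSAN had -0.50 ± 0.31 (adjusted p = 0.275), and its value was 0.18 with median centring. In the Calvin cycle, PRK, the phosphoribulokinase, had a log2 fold change of -0.14 ± 0.28 (adjusted p = 0.745), which was 0.01 on the deposited scale and 0.21 with median centring, and SBPASE was listed at 0 on all 8 arrays. SBPASE encodes an enzyme that green tissue uses, and the pairing of probes with genes was not checked here, so that every gene name rests on the annotation. In chlorophyll synthesis, CHLM had -0.18 ± 0.28 (adjusted p = 0.681). AT1G74470, the geranylgeranyl reductase, had 0.31 ± 0.20 (adjusted p = 0.290), and it passed on the deposited scale, with a log2 fold change of 0.92 (adjusted p = 0.0282), and with median centring, with 1.12 (adjusted p = 0.00587). The peroxiredoxin gene AT3G52960 had -0.48 ± 0.37 (adjusted p = 0.380), and -0.97 on the deposited scale (adjusted p = 0.0946).

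Across all probes, limma called 666 of the 3032 probes tested, 334 higher and 332 lower in red light, at an adjusted p under 0.05. Of the probes with 1 gene, 147 of 614 were called, 81 higher and 66 lower. Changes of over 2-fold made up 524 of the calls, 271 higher and 253 lower. The red and white samples did not overlap for 884 of the tested probes, or 29.2%. Chance gives 2.86% for 8 independent samples, which does not hold if similar samples are repeats of each other. With samples 1 and 2 of both groups set against samples 3 and 4, 476 probes did not overlap, or 15.7%. With white samples 1 and 2 and red samples 3 and 4 set against the rest, 199 did not, or 6.56%. For means of samples 1 and 2 and of samples 3 and 4, the groups did not overlap for 48.5% of the probes, where chance gives 33.3% for 2 units against 2. On the deposited scale 294 probes were higher and 467 lower, and with median centring 439 were higher and 326 lower, so that the balance of rises and falls followed the scaling. The median log2 fold change was -0.14 on the deposited scale, 0.06 with median centring and -0.03 after quantile normalization. Without white sample 1 the probes called lower numbered 212.

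Samples 1 and 2 of each group were close to each other, as were samples 3 and 4. Spearman correlations across probes, which are not independent replicates, were 0.910 to 0.947 within these pairs and 0.777 to 0.825 between the pairs of a group. With the pair as a random block, limma called 114 probes, 71 higher and 43 lower. With each pair averaged to 1 value, 2 against 2, limma called 0 probes, and 458 had an unadjusted p under 0.05. Of the 24 largest rises and falls, 10 passed with the pair as a random block: AT1G78620, AT5G40030, AT1G06730, AT5G38310, AT2G31920, AT3G02690, AT4G37230, AT1G02020, AT1G71910 and AT2G22890. PSBW and Z-ISO did not pass in that fit. Averaged pairs with the pair number as a block left the status of 32 of 34 genes named by the rule as it was, and 2 no longer passed. That fit ties pairs of the same number across the 2 groups, which rests on the data and not on the labels. Within samples 1 and 2 alone 1268 probes were called, and within samples 3 and 4 alone 1176. Their fold changes correlated across the 3032 probes with r = 0.459, and 63.5% of these probes had the same sign in both sets. AT4G13680, AT4G04370 and AT-HF did not pass in samples 1 and 2 alone, nor AT4G17070 in samples 3 and 4 alone. LHB1B2, PSAN, PSBY and PSB27 passed in the first set and PSB27 and AT3G52960 in the second, by tests that rest on the spread within pairs. A floor set for each array separately, as in the rule chosen first but also applied to low positive values, gave 1254 calls, 868 higher and 386 lower. Among them were 204 probes with an intensity of 0 on all 8 arrays.

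**Figure D2:**
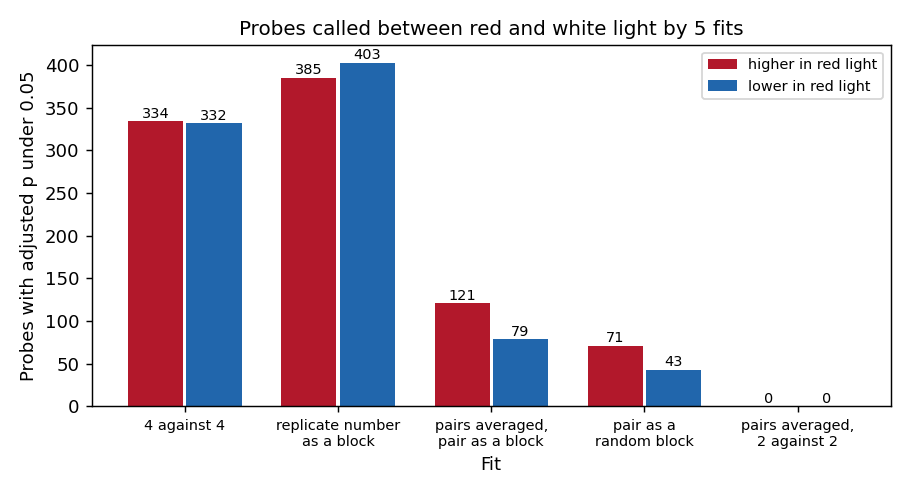
The vertical axis gives the number of probes with an adjusted p under 0.05 and the horizontal axis the fit, with bars for probes higher and lower in red light. The fit of 4 against 4 called 334 higher and 332 lower, the pair as a random block 71 and 43, and averaged pairs 0 and 0.

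The red samples also had a wider spread of intensities than the white samples. Over the 2565 probes above 0 and below the ceiling on all 8 arrays, the interquartile range of log2 intensity was 1.94 ± 0.16 in red light and 1.52 ± 0.19 in white light (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 70 splits allow; adjusted p = 0.0381 over 8 measures). These exact tests take the 8 samples as independent, and with each pair as 1 unit the smallest p would be 0.333. The 99th percentile was 12.2 ± 1.01 against 6.88 ± 1.37, and the number of probes at 0 was 592 ± 13.9 against 434 ± 39.2, each with the same exact p and adjusted p. Summed intensity was 2897 ± 336 against 2060 ± 354, again with the same exact p and adjusted p. The medians, 0.230 ± 0.0314 and 0.263 ± 0.0298, overlapped between the groups (exact p = 0.171, adjusted p = 0.196). Between same-numbered samples the red median was lower in 4 of 4, with differences from -0.0355 to -0.0309 (exact sign-flip p = 0.125, the smallest that 4 pairs allow).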

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

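The tests of technical repeats, of array scale, of values at 0 or at the ceiling, and of the spread of intensities on the calls were chosen after the results were seen. Those of spots shared by same-numbered arrays, of a few very bright probes and of other splits were chosen before their results were seen.

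In 2 of the 76 groups of 4 values without a value at the floor, 1 sample stood far from the others. Chance gives about 1 in 20 for 4 independent values, a rate that does not hold if similar samples are repeats of each other. The normalized log2 intensity of AT4G17070 in red sample 3 was 1.41, with the others from 3.13 to 3.37. AT1G29070 in white sample 3 was at 0.40, with the others from -0.53 to -0.43. AT4G13680 in white sample 3 was at -3.15 with the other white samples at the floor of -3.80, which sets it apart whatever its size.

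Samples 1 and 2, and samples 3 and 4, of each group resembled each other. The lowest Spearman correlation within a pair exceeded the highest between pairs of a group by 0.0846, which restates the resemblance. Array scale alone is argued against, since it leaves ranks alike and that difference taken the other way was -0.0846. Within-pair differences in white light correlated with those in red light across probes, with 0.261 as the lower of the 2 values, which ties samples of 1 number across groups and does not bear on the resemblance within pairs. Technical repeats of 1 array or RNA preparation and batches of separately grown plants cannot be told apart as sources of the pairs, since the labels do not describe them.

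The red arrays had a wider spread of intensities than the white arrays. Values at 0 or at the ceiling as its whole cause are argued against, since over the probes above 0 and below the ceiling on all 8 arrays the lowest red over white ratio of the interquartile range was 1.22. A few very bright probes do not either, since the lowest ratio of the SD without the brightest 1 in 100 was 1.17. Unstated scaling by the authors, labelling and hybridization, and the light condition itself may each have set the spread, and none of these was tested.

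The calls between red and white light were weighed against that spread and against chance. A wider spread as their whole cause is argued against, since a share of 0.671 of the calls on the deposited scale was also called after quantile normalization. Of 35 splits of the 8 samples, 1 gave as many calls, the real one with 666, and the highest other gave 109. That share would argue against chance only if the 8 samples were exchangeable. The ties within pairs and between same-numbered samples go against that, so that chance is not excluded. That other split set samples 1 and 2 against 3 and 4, and among the 8 splits that part all same-numbered samples the highest other gave 7. Neither these 8 splits nor the 3 that keep the pairs together are enough for a share under 0.05. For pairs that are technical repeats the light effect may rest on 2 units per group.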

How the results depend on the processing

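The floor per array was the rule chosen first, except that positive values below the floor were also raised to it. The common floor of the reported fit and the fits built on pairs of samples were chosen after seeing the data, and the other alternatives before. Under 8 other ways of scaling, flooring, filtering, weighting or averaging all 8 samples, calls numbered 615 to 765, and no call shared with the reported fit changed sign. Of the 666 reported calls, 511 were also made on the deposited scale, 545 with median centring and 553 with the higher floor. The rest of these ways shared 602 to 665 calls with the reported fit. The replicate block gave 788 calls, 385 higher and 403 lower, and among the genes named in the text it changed the calls of PSB27, GH9B11, LPA19, SRX and APS4 and no other. A floor per array gave 1254 calls, 868 of them higher, because the floors differ between groups and 407 more probes were tested. Averaged pairs gave 0 calls, 0 higher and 0 lower, in limma, with 458 at an unadjusted p under 0.05. Averaged pairs with the pair number as a block gave 200, 121 higher and 79 lower. The pair as a random block gave 114, 71 higher and 43 lower. Samples 1 and 2 alone gave 1268, 632 higher and 636 lower, and samples 3 and 4 alone gave 1176, 567 higher and 609 lower. The cause of the differences among these fits on pairs was not tested, and if the pairs are technical repeats the p-values of the last 2 may be too small. Leaving out 1 sample gave 455 (without white sample 1) to 614 calls, 241 to 295 higher and 212 to 319 lower. The planned list tests, and their alternatives, were not run, since no list had 5 measured members. Over 1 probe in 10 lay at the floor on all 8 arrays and gives no comparison.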

Other observations

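The lists in this part were drawn from the gene symbols on the array after its coverage was seen, and the fold changes of AT-HF and GH9B12 were known before their lists were made. Of all tested probes with 1 gene, 147 of 614 were called, or 23.9%, so that some calls in any list come with that share. Among 7 transcription regulators tested, AGL54, a MADS-box gene, rose with a log2 fold change of 1.01 ± 0.20 (SE, limma adjusted p = 0.00874), and TCP15, a regulator of cell proliferation, rose with 1.38 ± 0.34 (adjusted p = 0.0215). IAA31, an auxin-response repressor, fell by 0.76 (SE 0.20, adjusted p = 0.0279), and the other 4 did not pass. Among 7 genes of cofactor and amino acid metabolism, HEMA3, a glutamyl-tRNA reductase of tetrapyrrole synthesis, rose with 1.46 ± 0.37 (adjusted p = 0.0243). SIRB, the ferrochelatase of siroheme synthesis, fell by 0.84 (SE 0.24, adjusted p = 0.0334), AT-HF fell by 1.78, and the other 4 did not pass. With the pair as a random block none of these 6 passed, with adjusted p from 0.0935 for AGL54 to 0.352 for AT-HF.

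Among 5 cell wall genes, the glycosyl hydrolases GH9B11 and GH9B12 fell by 1.07 (SE 0.27, adjusted p = 0.0243) and 1.62 (SE 0.40, adjusted p = 0.0212), and the other 3 did not pass. With the replicate number as a block the adjusted p of GH9B11 was 0.0558, while LPA19 (0.0228), SRX (0.0496) and APS4 (0.0166), which did not pass without it, passed. With the pair as a random block these 3 had adjusted p of 0.215, 0.592 and 0.412. Of 6 redox enzymes, GLDH, which makes ascorbate, fell by 1.15 (SE 0.35, adjusted p = 0.0480), and the other 5 did not pass. Of 9 plastid RNA processing, chaperonin and membrane assembly genes, SECE1, of the thylakoid translocase, fell by 1.04 (SE 0.22, adjusted p = 0.0126), and the other 8 did not pass. None of these 4 genes passed with the pair as a random block, with adjusted p of 0.149 for GH9B11, 0.0920 for GH9B12, 0.183 for GLDH and 0.161 for SECE1. The 4 tested genes of the list of NDH complex and chlororespiration factors did not pass, with log2 fold changes of -0.08 for NdhS, 0.36 for CRR21 and -0.10 for PIFI, while NdhN was at or below the floor on all 4 white and 3 of the 4 red arrays.

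A shift of a whole list was tested as a hypothesis with camera over 6 lists, including a pool, made later, of the lists fixed beforehand, and none passed. The lowest adjusted p was 0.600, for the cell wall list (mean log2 fold change -0.46) and the redox list (-0.59), and with an estimated correlation the adjusted p of both was 0.902. It was 0.827 for the transcription regulators and 0.901 for the pooled, the plastid and the cofactor lists. The exact two-sided permutation p of the list mean was 0.0286, the smallest possible, for the redox enzymes and the transcription regulators (adjusted p = 0.0857 over 6 lists), and their fry adjusted p was 0.0610. These list tests take the 8 samples as independent, and with each pair as 1 unit the smallest exact p would be 0.333.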
